A study of Schizosaccharomyces pombe with 8 samples.

How the data were processed

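H3K9me2 ChIP DNA and whole cell extract DNA (input) of 8 cultures were each hybridised to 1 two-colour Agilent tiling array with 41551 non-control probes about 300 bp apart. Per the labels, cells were fixed for 30 min, ChIP DNA was labelled with Cy5 (red) and input DNA with Cy3 (green). Cultures grew in YEA medium, or, for the low glucose condition, in EMM medium with 0.5% glucose. Per the file headers, the intensity values (processed signals) had been background-subtracted and linearly dye-normalised in Agilent Feature Extraction, and the raw median intensities had not been normalised. Per the file headers, the log10 values are the log10 ratio of the red to the green processed signal, without centring. The log2 values of the series matrix were deposited by the authors as the ratio of red to green processed signal, without centring. Per the submitters' processing notes, the software was Feature Extraction 11.0.1.1, while the headers of the 3 arrays of slide 1 name version 10.7.3.1. No probe alignment applies, and the genome build of the probe positions is not given in the sources used here.

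The matrix was compared with the scanner files. In 7 of its 8 columns 100% of probes equalled the log2 ratio of the scanner file within 0.001. In the WT column 0.164% did, with Pearson r 0.839 and Spearman rho 0.426 across probes, which are not independent replicates. The column correlated by rank more with the rrp6∆ red1∆ array (rho 0.462), but by Pearson r less (0.813). The scanner files were therefore used throughout, with the matrix as an alternative. The medians of the matrix columns were -0.036 for WT, -0.0715 for rrp6∆, -0.0253 for rrp6∆ ago1∆, -0.0718 for rrp6∆ red1∆, -0.103 for rrp6∆ pla1-37, -0.0876 for rrp6∆ pab2∆, -0.0978 for WT in low glucose and -0.138 for ago1∆ in low glucose.

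For each array the log2 ratio of processed ChIP to processed input signal was taken, probes marked as outliers by the scanner software were left out, and the values were centred on the array's median. No loess and no quantile normalisation was applied. Before centring, the medians lay between -0.21 and -0.03. The SD of differences between neighbouring probes lay between 0.14 and 0.29. The number of arrays limits the precision, and no test across replicates was possible.

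Gene names came from the ASM294v3 annotation. Because the build of the probe positions was unknown, array positions were registered to that sequence by matching the GC content of the reference to the input signal, in 84 windows of 150 kb with shifts of up to 8 kb. The best match exceeded the matches elsewhere in 25 and 12 windows of the left and right arms of chromosome I, 11 and 19 of chromosome II and 7 and 10 of chromosome III, which are all the windows. The median shifts were -770, 4485, -820, -1680, 90 and -810 bp in the same order of arms. All positions printed are those of the array. Probe classes were 18457 probes on chromosome I, 14836 on II, 7958 on III, 110 on the mating-type contig, 61 on the mitochondrial genome and 129 on the subtelomeric pNSU clones. Of the registered probes, 849 had less than 50% unique sequence, counted in 40-mers.

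A gene's difference was the median over its probes of the difference between 2 arrays, and it was called higher or lower with at least 3 probes, a difference of at least 1.5-fold and 75% of probes in the same direction. Domains were runs of at least 5 consecutive probes whose running median over 5 probes reached 1.5-fold, with gaps of up to 2 kb, and their mirror image below the centre served as background. Constitutive heterochromatin was the WT domains merged over 5 kb that reached 20 kb, the outer 100 kb of chromosomes I and II, the mating-type contig and the pNSU clones. Gene counts over the genome are for genes outside it and leave out the loci deleted in the strains (rrp6, ago1, red1, pab2). List counts and list medians include members inside it, while the random lists were drawn from outside. In rrp6∆ against WT these members were 2 of 22 recombination, 2 of 4 phosphate, 2 of 8 hexose, 2 of 13 metal, 3 of 16 permease, 3 of 49 ribosomal protein and 1 of 7 marker genes. Each pericentromere was the widest gap between protein-coding genes within 300 kb of the arm boundary (33.9 kb on I, 52.3 kb on II and 79.1 kb on III). The plan had been the longest WT domain where the reference gave no centromere, but on chromosome I this lay at the end. The input at each deleted gene was compared with the arrays whose labels do not name its deletion. Intervals over genes are 95% bootstrap intervals, with 2 exceptions. Those of the odd and even split and of the results flagged for a closer look are 95% order-statistic intervals of the median. Both kinds treat genes or probes as independent and say nothing of variation between cultures.

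The comparisons, gene lists, settings and the rule for named genes were fixed before the data were examined. For each comparison the text names the 12 largest called higher and the 8 largest called lower of the single-copy protein-coding genes, with Tf2 elements and repeats treated as a class. It also names the 3 members of each list with the largest absolute difference, the targeted loci and the 5 longest domains gained and lost, and it follows the 20 largest gains of rrp6∆ through the double mutants. Not every gene under this rule is given a value in the text. The lists were 13 meiotic transcripts under Mmi1 and Red1 control, 25 mating and signalling genes, 26 genes of recombination and sporulation, 91 mug genes, 13 Tf2 elements, 4 phosphate genes, 8 hexose transporter genes, 13 metal transport genes and 16 permease genes. Further lists were 12 stress and glucose-repressed genes, 131 ribosomal protein and 17 housekeeping genes as euchromatic controls, 13 loci of the RNAi and H3K9 methylation machinery, 54 snoRNA genes, 12 names of mating-type cassette genes (6 found and 0 measured), 5 targeted loci, 7 marker loci and 123 genes of the chromosome ends. List medians were set against 10000 random lists of the same size matched on input intensity, and 40 of 110 medians lay outside the central 95%.

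Procedures were tested on simulated data with the probe spread and the gene spread of each comparison. The gene spread was taken from the observed differences, so real changes widen it. The number of simulated calls is therefore not an independent background. Of 50 planted changes per size, 24 to 28 were recovered at 1.5-fold, 43 to 50 at 2-fold and 48 to 50 at 3-fold, and 0 were called in the opposite direction. Of 20 planted domains, 20 were found in each comparison but 18 for WT in low glucose against WT and 15 for ago1∆ against WT in low glucose. The overlap of gains was set against lists of the same sizes in 1000 simulations of unchanged arrays that share the WT array, with normal noise of the observed spread. The medians over gains were set against 1000 simulations of the same kind. Matching the list sizes and simulating these medians were added after the results were seen.

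The alternatives were mode centring, no centring, scaling by the median absolute deviation (MAD), loess within arrays, normexp background with offset 50, the series matrix, leaving out non-unique or dim probes, a 2-fold threshold, 2 probes per gene with 3 per domain, flanks of 500 bp, a running mean, unmatched lists and a split into odd and even probes. Chosen after seeing the data were keeping the outlier probes, moving the registration by 150 bp in each direction and leaving out genes with lost input. The files hold no mean signals, so raw median signals took their place in normexp and in the deletion check. Computing used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 for normexp and loess.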

Results

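The study measured where dimethylated lysine 9 of histone H3 (H3K9me2), the histone mark of heterochromatin, lies along the genome of fission yeast, Schizosaccharomyces pombe. In each of 8 cultures, chromatin was immunoprecipitated with an antibody against H3K9me2 (ChIP), and the recovered DNA was hybridised together with DNA of the whole cell extract (the input) to a tiling array with 41551 probes about 300 bp apart. Each culture has 1 array: wild type (WT), rrp6∆, the 4 double mutants rrp6∆ ago1∆, rrp6∆ red1∆, rrp6∆ pla1-37 and rrp6∆ pab2∆, and WT and ago1∆ grown in low glucose. Rrp6 is an exonuclease of the nuclear exosome, which degrades RNA, and Ago1 is the Argonaute protein of the RNA interference (RNAi) pathway. Red1 acts in the elimination of meiotic transcripts in growing cells, Pla1 is the poly(A) polymerase (pla1-37 is a mutant allele of its gene), and Pab2 is a nuclear poly(A)-binding protein. The title of the series puts the question as how RNAi and the RNA-processing machinery bring silencing to developmental genes and to retrotransposons. Levels given here are log2 of ChIP over input, centred on each array's median, and the ± value is the standard deviation (SD) between the probes of a gene or region. With 1 array per group there is no replicate error and no p-value. Positions are those of the array's probes, whose genome build is not given in the sources used here.

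The median raw ChIP signal fell across the slides, from 15372.5 in WT, 14575.5 in rrp6∆ and 12965.5 in rrp6∆ ago1∆, all on slide 1, to 7071 in rrp6∆ red1∆ on slide 2. It was 2282 in rrp6∆ pla1-37 and 2527.5 in rrp6∆ pab2∆, both on slide 3, 1439 in WT in low glucose on slide 4 and 1235 in ago1∆ in low glucose on slide 5. Input medians lay between 13302 and 24846, and no spot was saturated. Between 1 and 34 probes per array were not well above background in the input. The scanner software marked 14791 probes (35.6%) of the WT low glucose array as outliers, against 106 to 768 on the other arrays.

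The deleted genes were checked in the input channel. At rrp6 the input lay below the arrays without that deletion by medians of -8.64 in rrp6∆, -7.58 in rrp6∆ ago1∆, -9.10 in rrp6∆ red1∆, -9.18 in rrp6∆ pla1-37 and -9.67 in rrp6∆ pab2∆. At ago1 it lay at -7.33 in rrp6∆ ago1∆ and -9.81 in ago1∆ in low glucose, at red1 at -8.82 in rrp6∆ red1∆, and at pab2 at -5.59 in rrp6∆ pab2∆. The 9 values match the labels. The allele pla1-37 cannot be checked by signal. The input of rrp6∆ pla1-37 was also nearly absent over 8.1 kb of chromosome I that its label does not name (2932500 to 2940600, 27 probes, median -7.97), which holds cao1 and cbm1. Ratios at deleted genes and at cao1 and cbm1 in rrp6∆ pla1-37 therefore rest on almost no input.

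In WT, H3K9me2 was concentrated in the known heterochromatin. The pericentromeres had a median level of 6.40, the mating-type region 2.40 and the outer 100 kb of chromosomes I and II 1.18. Altogether 110 domains covered 907.5 kb, and 47 of them lay outside constitutive heterochromatin, while the mirror image (domains below the centre) gave 22 domains over 52.5 kb. Among single genes, mei4, which encodes a meiotic transcription factor, stood at 3.88, ssm4, a meiotic microtubule-associated protein, at 3.32 and mcp7, a meiotic recombination gene, at 2.85. The locus ura4, a common selection marker, stood at 6.27 over 4 probes.

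**Figure D1:**
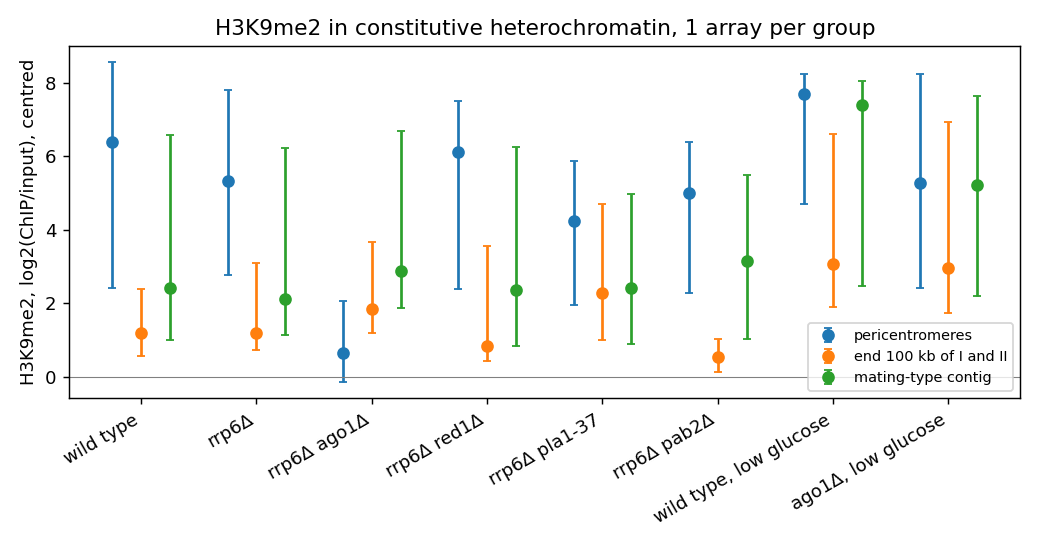
Median log2 ChIP over input per array (y axis) with bars from the lower to the upper quartile of probes, for the pericentromeres, the outer 100 kb of chromosomes I and II and the mating-type contig, 1 point per array. The pericentromeres lie at 0.66 in rrp6∆ ago1∆ against 4.23 to 7.68 in the 7 other arrays.

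The comparison of rrp6∆ with WT asks where H3K9me2 changes when the nuclear exosome lacks Rrp6. H3K9me2 rose at 114 genes outside constitutive heterochromatin and fell at 15, of 4580 genes measured in all, the largest gains lying in a block of chromosome III and all the measured Tf2 retrotransposons rising. The strongest gain was a block of chromosome III around ste6, a guanine nucleotide exchange factor for Ras1 needed for mating: ste6 (1767000 to 1770000) rose by 4.22 ± 0.38 (10 probes) to a level of 4.39. All 9 measured Tf2 elements rose, with a median difference of 2.07. These elements are repeats, left out with the non-unique probes, so their 9 values are not independent, here or in later comparisons. In the opposite direction, the meiotic genes mei4, mcp7 and ssm4 lost most of the H3K9me2 that they carried in WT.

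The genes beside ste6 rose with it. The differences were 4.94 ± 0.33 at glm2, 4.61 ± 0.28 at rmr1 and 4.56 ± 0.22 at mme1, and 3.51 ± 0.23 at mic26, 3.23 ± 0.29 at pre8, a proteasome subunit gene, and 3.01 ± 0.20 at wss2. The domain spanned 30.6 kb (III 1758900 to 1789500, median difference 2.54) and ran from rib5 to SPCC1442.11C. Over ste6, glm2, mme1 and rmr1 the ChIP channel rose by a median of 3.19 and the input channel changed by -1.27 (33 probes). The other large single-gene gains lay in a few blocks of chromosome I. At lcb4, a sphingoid base kinase gene, the difference was 2.58 ± 0.54, at SPAC4A8.06C 2.51 ± 0.20 and at myp2, a type II myosin heavy chain gene, 2.37 ± 0.34 (21 probes). Elsewhere pvg2, a cell-surface galactose modification gene, rose by 2.45 ± 0.18 and cbm1 by 2.44 ± 0.27.

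Among the longest gained domains, the one over puf6, ade5 and the SPCC569 genes near the right end of chromosome III reached 38.1 kb (2410800 to 2448900, median 1.04). A domain over Tf2-3, cao1 and cbm1 covered 19.5 kb (I 2927700 to 2947200, 2.12), one over SPCP20C8.01C and SPCP20C8.02C at the left end of chromosome III 18.6 kb (16200 to 34800, 0.96), and one over msm1, pvg2, Tf2-6 and mak2 16.2 kb (I 4012800 to 4029000, 1.12). Domains gained numbered 62 (43 outside constitutive heterochromatin, 402 kb in all), against 30 lost (10 outside, 169.8 kb).

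**Figure D2:**
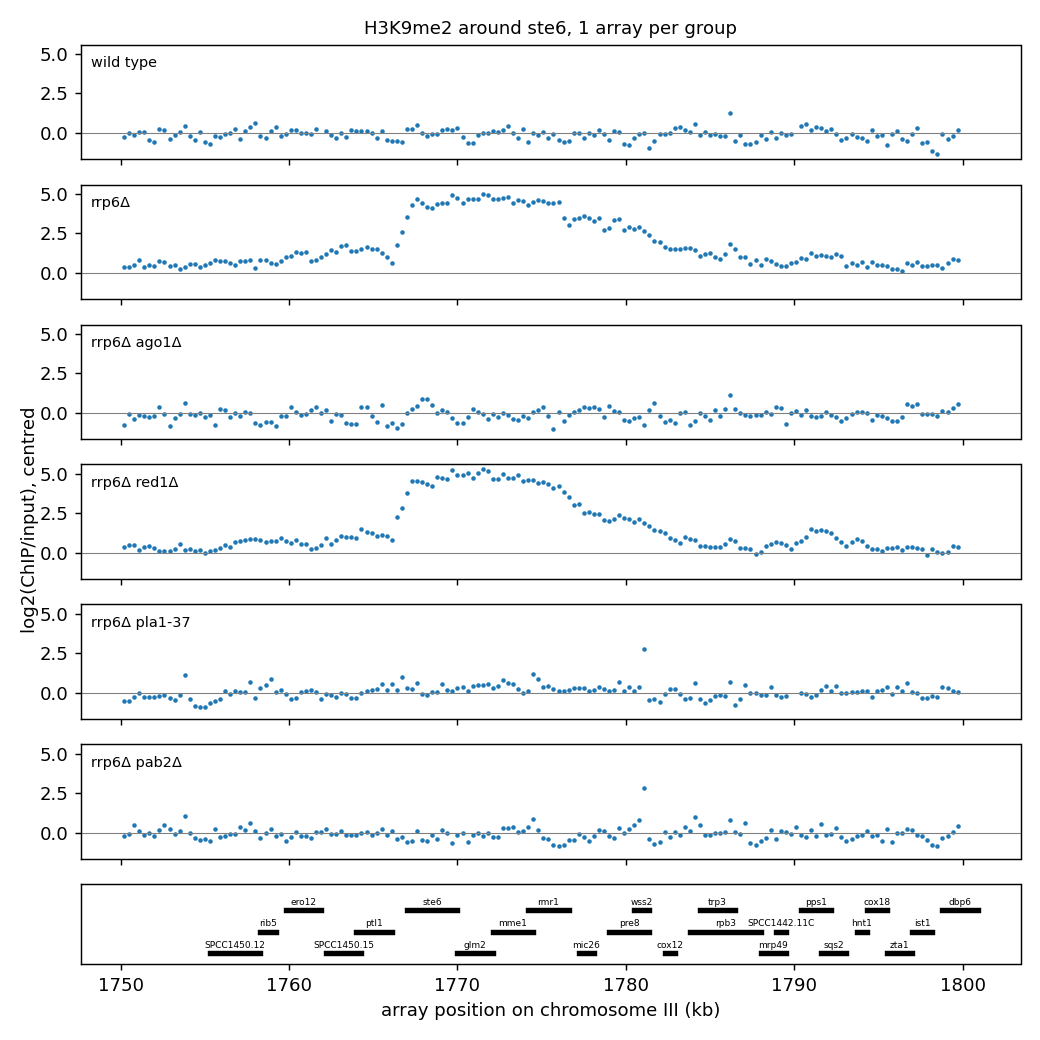
Centred log2 ChIP over input (y axis) along chromosome III around ste6 (x axis, array positions in kb) for WT, rrp6∆ and the 4 double mutants, with the genes drawn under the tracks. The block around ste6 stands out in rrp6∆, where the ste6 level is 4.39, and in rrp6∆ red1∆, where it is 4.52.

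Of the list members named in this text, rec6, isp3, pho1, pho84, ght3, ght7, str3, per1, put4, cat1, rpl1002, rps402, rpl401 and lys1 lie inside constitutive heterochromatin and are counted in their lists. Of the lists fixed beforehand, the Tf2 and phosphate lists shifted most. In the Tf2 list Tf2-1 rose by 2.40 ± 0.24, Tf2-5 by 2.16 ± 0.21 and Tf2-12 by 2.10 ± 0.21. In the phosphate list 3 of 4 members rose (list median 0.68), namely tgp1, a glycerophosphodiester transporter gene, by 0.80 ± 0.32, the phosphate transporter gene pho84 by 0.76 ± 0.48 and the acid phosphatase gene pho1 by 0.60 ± 0.13. Since pho84 and pho1 lie in the outer 100 kb of chromosome II, tgp1 alone of the 3 is euchromatic, and the list median without them was 0.34. Of 10000 random lists matched on input intensity, 100% had medians below that of the Tf2 list and 99.99% below that of the phosphate list. Neither is a comparison of like sets. The random lists take every gene as separate, unlike the Tf2 repeats, and leave out constitutive heterochromatin, which holds pho84 and pho1. In the list of meiotic transcripts under Mmi1 and Red1 control, 4 of 13 genes fell and 1 rose. There mei4 fell by 3.51 ± 0.69 to 0.42, mcp7 by 3.33 ± 0.55 to -0.36, ssm4 by 3.28 ± 0.96 to 0.08 and mug9 by 1.34 ± 0.54 to -0.43. At mei4 the ChIP channel changed by -2.33 and the input by 1.12. Of 79 mug genes, which are up-regulated in meiosis, 2 rose and 2 fell, with mug5 at 1.51 ± 0.50 and mug143 at 0.66 ± 0.53.

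In the mating list 2 of 21 genes rose, ste6 and the pheromone-response MAP kinase gene spk1 (1.07 ± 0.19). None of 22 genes for recombination and sporulation passed the call, with rec6 at -0.40 and rec12 at 0.39. None of 8 hexose transporter genes (ght1 at -0.39), none of 13 metal transport genes (sib2 at -0.38) and 1 of 16 permease genes passed, aat1 at 0.61 ± 0.35. The hexose list median was -0.24, with 0.97% of matched random lists below it. None of 11 stress genes (hsp104 at -0.37) and none of 13 loci of the RNAi and H3K9 methylation machinery (chp2 at 0.43, rdp1 at 0.30) passed, nor did the only measured snoRNA gene, sno1 (0.10). The euchromatic control lists gave 2 higher of 49 ribosomal protein genes (rpl1002, inside the pericentromeric domain of chromosome I, at 0.75 ± 0.44, and rpl1001 at 0.64 ± 0.28) and 1 lower of 15 housekeeping genes (fba1 at -0.61 ± 0.06). Their list medians were -0.14 (0.03% of random lists below, but 0.08 with series matrix values) and -0.17 (0.34% below). Among 7 marker loci lys1 rose by 0.99 ± 0.23, while ura4 differed by -0.93 ± 0.16. That ura4 direction, and that of pre6 (-0.88 ± 0.34), a proteasome gene, turns to 0.96 and 0.29 with the values of the series matrix. Further lower genes were ubp8 beside mcp7 (-2.16 ± 1.11) and SPAC8C9.04 (-2.05 ± 0.93). Of the 5 targeted loci, ago1, red1, pla1 and pab2 lay between -0.09 and 0.12, and the value of 1.38 at rrp6 rests on nearly absent input. None of the mating-type cassette genes had enough probes to be measured.

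The main lost domains matched these genes: but1, ssm4 and tpr1 (I 4528200 to 4533300, -1.18), cdk9, mei4 and act1 (II 1472700 to 1476600, -2.70), mcp7 and ubp8 (I 578400 to 582000, -2.27) and SPAC8C9.04 (I 3647700 to 3650400, -2.05). A further lost domain lay in the pericentromere of chromosome III (1110300 to 1114800, -0.71). Constitutive heterochromatin differed less. The median difference was -0.49 at the pericentromeres, -0.17 at the chromosome ends and -0.16 at the mating-type contig, with opposite signs under normexp background (0.19 and 0.11 at the pericentromeres and the contig), MAD scaling (0.16 and 0.31) and series matrix values (1.96, 1.00 and 1.36 for the 3 regions). Within the ends SPBPB10D8.04C, SPBPB10D8.05C and SPBPB10D8.06C gained 4.16 ± 0.55, 4.05 ± 0.35 and 4.02 ± 0.02, while of 90 end genes 9 rose and 17 fell (median -0.15, but 0.89 with series matrix values).

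In simulated arrays with the spread of these data but no change, 31 of 4173 genes (0.743%) passed the call in this comparison. The WT column of the series matrix is not the WT scanner file (Pearson r 0.839 across probes), and with it 205 genes rose and 28 fell, of which 89 of the 114 and 4 of the 15 were the same genes. In that column mei4, ssm4 and mcp7 stood at 1.58, 0.88 and 1.13, so their WT levels, and with them the size of their losses, depend on which WT values are used.

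**Figure D3:**
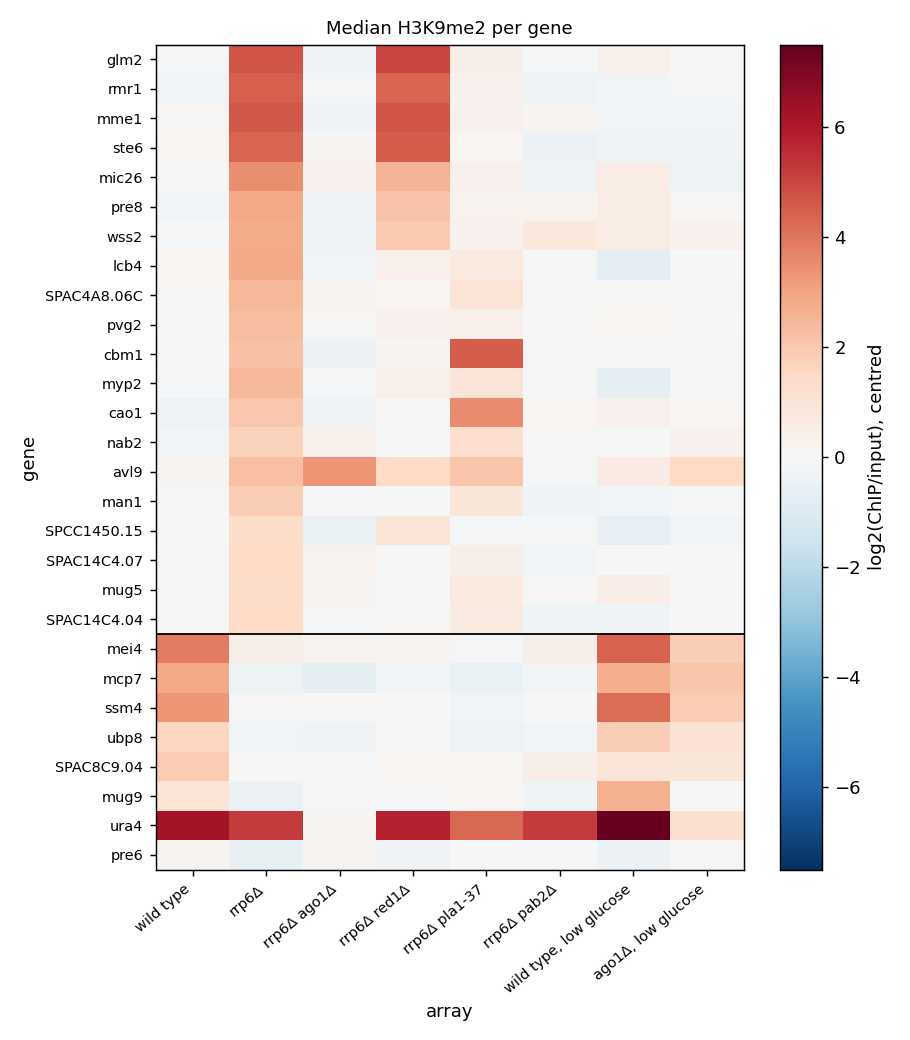
Heatmap of centred log2 ChIP over input (colour, from -7.5 to 7.5) for the 20 largest gains of rrp6∆ and its 8 largest falls (vertical) in the 8 arrays (horizontal). The ste6 block is high in rrp6∆ and rrp6∆ red1∆, and mei4 is high in WT (3.88) and in WT in low glucose (4.40).

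The comparison of rrp6∆ ago1∆ with rrp6∆ asks which H3K9me2 of rrp6∆ depends on Argonaute. Without ago1, the ste6 block returned to the WT level, the Tf2 elements and most other rrp6∆ gains fell, and the pericentromeres lost most of their signal. Over the 114 genes gained in rrp6∆ the median difference was -0.81 (95% interval over genes -0.99 to -0.68, 113 measured) from rrp6∆ and 0.15 (0.10 to 0.26) from WT. Of these genes 74 fell and 8 rose. Genes selected as gains on 1 array lie lower on another by selection alone: simulated arrays without any change gave about 5 gains, with medians of -0.31, -0.39, -0.45 and -0.44 from rrp6∆ for the double mutants with ago1∆, red1∆, pla1-37 and pab2∆. For pla1-37 the observed median lay within the central 95% of the simulations (-0.80 to -0.10), though 50.4% of its genes fell against 32.5% simulated. Medians over about 5 genes scatter more than one over 113, so for pla1-37 the simulations cannot decide whether selection explains the fall. With ago1∆, red1∆ and pab2∆ the observed medians lay below the central 95% (-0.57 to -0.03, -0.59 to -0.18 and -0.71 to -0.17). For these double mutants, selection under normal noise is argued against as the whole cause, within 1 array per strain. For genes selected on odd probes, the medians on even probes were -0.86, -0.75, -0.84 and -0.98 in the same order (73 genes). Even probes share the array, so this split removes selected probe noise only. The pericentromeres stood at 0.66 against 5.33 in rrp6∆, with a median difference of -3.58 ± 1.64 (320 probes), while the chromosome ends (0.80) lay higher under every scaling tried and the mating-type contig (0.77) under all but MAD scaling (-0.20).

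Of 4582 genes measured, 134 fell and 98 rose outside constitutive heterochromatin. The largest falls were glm2 (-5.05 ± 0.34), ura4 (-5.05 ± 0.43), mme1 (-4.79 ± 0.15), rmr1 (-4.46 ± 0.42), ste6 (-4.16 ± 0.57), pre8 (-3.20 ± 0.33), wss2 (-3.19 ± 0.19) and mic26 (-3.18 ± 0.07). The domain lost around ste6 covered 32.7 kb (III 1756800 to 1789500, -2.16). Others lost were Tf2-3 with cao1 (I 2927700 to 2946300, -2.02), mek1 to mug5 (I 5226000 to 5243100, -1.07), myp2 with lcb4 (I 2546700 to 2562300, -2.27) and spk1 with pac2 (I 2997600 to 3012000, -1.08). All 9 Tf2 elements fell (median -1.90), with Tf2-1 at -2.09 ± 0.26. Of the 20 largest rrp6∆ gains, 19 fell and 1, avl9, rose further by 1.19 ± 0.16 to a level of 3.30.

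The gains in rrp6∆ ago1∆ were led by SPCC1884.01 (1.55 ± 0.42), cup1 (1.49 ± 0.12), the enolase gene eno101 (1.47 ± 0.62), hsp3101 (1.30 ± 0.09), SPCP20C8.02C (1.24 ± 0.05) and SPBC17G9.12C (1.23 ± 0.49). Next came SPCC757.05C (1.11 ± 0.74), arc1 (1.08 ± 0.22), ivn1 (0.98 ± 0.25), SPAC1039.02 (0.94 ± 0.36) and car1 (0.93 ± 0.21). The longest gained domains were SPCC569.02C with SPCC569.01C (III 2433600 to 2446200, 1.12), pyr1 to cut2 (II 2192700 to 2205300, 1.25) and SPCC1884.01 (III 33000 to 42600, 1.72), followed by SPBPJ4664.02 (II 690000 to 698400, 0.69) and ctt1 (III 55200 to 61200, 0.75). Of 88 end genes 61 rose and 3 fell, the 3 being SPBPB10D8.04C (-2.54), SPBPB10D8.05C (-2.42) and SPBPB10D8.06C (-2.38).

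Most lists held few calls. The recombination gene rec6 fell by 1.75 ± 0.32 and the spore gene isp3 rose by 0.96 ± 0.17 (1 and 1 of 22), mek1 fell by 0.72 ± 0.11 among the Mmi1 and Red1 targets, spk1 fell with ste6 in the mating list, and 5 mug genes fell, among them mug5 (-1.12 ± 0.26). Of the permease genes, per1 fell by 3.26 ± 0.43, and car1 and isp5 (0.61 ± 0.22) rose. In the phosphate list tgp1 fell by 0.90 ± 0.14, in the hexose list ght7 rose by 0.75 ± 0.24, in the stress list the catalase gene ctt1 rose by 0.79 ± 0.16, and no metal transport gene passed. Of the control lists, 6 ribosomal protein genes rose and 2 fell of 51 (rpl401 at 0.88, rpl1002 at -1.49), and 3 of 15 housekeeping genes rose (eno101, pgk1 at 0.82, adh1 at 0.72). The RNAi gene rdp1 fell by 0.60 ± 0.39 and the marker lys1 by 2.57 ± 0.25. Without centring 128 genes were higher and 115 lower, with MAD scaling 51 and 128, and the simulation without change gave 117 calls among 4177 genes (2.80%).

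The comparison of rrp6∆ red1∆ with rrp6∆ asks which of this H3K9me2 depends on Red1. Removing red1 lowered H3K9me2 at the Tf2 elements and most other rrp6∆ gains, but left the core of the ste6 block at its rrp6∆ level. The median over the 114 rrp6∆ gains was -0.71 (-0.81 to -0.55) from rrp6∆ and 0.29 (0.21 to 0.37) from WT. Of them 66 fell and 0 rose. In the ste6 core the differences were 0.22 ± 0.17 at ste6, 0.30 at glm2, 0.15 at mme1 and -0.04 at rmr1, none of them called, and with loess ste6 and mme1 stood at -0.01 and -0.04.

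Of 4588 genes measured, 82 fell and 14 rose outside constitutive heterochromatin, and of 206 inside it 17 fell and 13 rose. The largest falls were lcb4 (-2.38 ± 0.73), SPAC4A8.06C (-2.31 ± 0.43), cbm1 (-2.03 ± 0.19), pvg2 (-1.99 ± 0.17), myp2 (-1.97 ± 0.33), the copper amine oxidase gene cao1 (-1.94 ± 0.24), nab2 (-1.83 ± 0.27) and man1 (-1.72 ± 0.45). At the flank of the ste6 block mic26 (-0.88), pre8 (-0.80) and wss2 (-0.79) fell in part. Lost domains lay over Tf2-3 with cao1 (I 2928600 to 2948700, -1.57), SPCC569.05C to SPCC569.01C (III 2423400 to 2439900, -0.91), puf6 to SPCC569.06 (III 2410200 to 2422500, -1.13), myp2 with lcb4 (I 2546700 to 2562900, -1.88) and mek1 to mug5 (I 5226300 to 5242500, -1.34). Of the ste6 domain, 84.8% of the rrp6∆ gain was kept, against 17.5% of the domain around cao1, 4.83% around pvg2, 7.64% around SPCP20C8.02C and 4.55% around SPCC569.05C.

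All 9 Tf2 elements fell (median -1.75) and so did 3 of 4 phosphate genes, pho1 by 0.96 ± 0.34, tgp1 by 0.74 ± 0.17 and pho84 by 0.68 ± 0.24, of which pho1 and pho84 lie at the chromosome end. Also lower were mek1 (-0.68 ± 0.04), spk1 (-0.93 ± 0.31), mug5 (-1.41 ± 0.34), rpl1002 (-1.10 ± 0.23), rpl1001 (-0.73 ± 0.25) and lys1 (-1.38 ± 0.17). The genes that rose did so by little: rhb1, a Ras-like GTPase gene, by 0.78 ± 0.45, mrpl15 by 0.76 ± 0.51, cif1 by 0.76 ± 0.18, slu7 by 0.74 ± 0.22 and atp4 by 0.71 ± 0.21. Then came uch2 (0.70), wss1 (0.70), SPBC685.03 (0.69), the eisosome gene pil1 (0.68), dcn1 (0.66), ura4 (0.66), SPBC557.02C (0.64) and the stress gene gpd1 (0.62 ± 0.27). No recombination, hexose, metal, permease, housekeeping or RNAi gene of the lists passed, though the hexose list median was 0.33, with 99.79% of matched random lists below it. Of 89 end genes 13 rose and 8 fell. The pericentromere difference of -0.30 turns to 0.37 with MAD scaling. Mitochondrial probes, which have no histones, lay 0.71 higher than in rrp6∆ (60 probes). The split of higher and lower genes was 194 and 197 with normexp background and 46 and 109 with MAD scaling. Genotype and slide cannot be told apart here, since this array is alone on its slide, and 51 of 4182 unchanged simulated genes (1.22%) passed the call.

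The comparison of rrp6∆ pla1-37 with rrp6∆ asks the same of the poly(A) polymerase. In this array the ste6 block and the Tf2 elements lost H3K9me2, while 2 long blocks, around red1 and around tgp1, gained it from median levels of -0.03 and 0.41 in rrp6∆. The block on chromosome I (5062200 to 5092800, 30.6 kb, median 2.67) runs from psp3 to atl1 and holds red1 itself (2.90 ± 0.19). The block on chromosome II (342000 to 369300, 27.3 kb, median 2.26) holds tgp1, which rose by 2.54 ± 0.35 to a level of 3.58. Over the 114 rrp6∆ gains the median was -0.70 (-0.85 to -0.45, 113 measured) from rrp6∆ and 0.41 (0.27 to 0.51) from WT, with 57 genes lower and 6 higher.

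Of 4586 genes measured, 186 rose and 186 fell outside constitutive heterochromatin, and of 207 inside it 51 rose and 31 fell. In the red1 block, och1, a mannosyltransferase gene, rose by 3.12 ± 0.28, win1, a stress MAP kinase kinase kinase gene, by 3.01 ± 0.30 (16 probes), asa1 by 3.0 ± 0.15, mcp3 by 2.82 ± 0.33 and etd1 by 2.38 ± 0.27. In the tgp1 block, SPBC1271.07C rose by 2.66 ± 0.22, SPBC1271.05C by 2.53 ± 0.40, SPBC1271.08C by 2.43 ± 0.19, SPBC1271.10C by 2.38 ± 0.14 and pet802 by 2.38 ± 0.27. Smaller gained domains lay over alg14 to rbm10 (I 1503600 to 1515600, 1.00), ssz1 to sec21 (I 1516200 to 1525200, 0.95) and fhn1 (II 522300 to 528600, 0.74). The genes dak2, SPAC977.17 and SPAC977.15 at a chromosome end gained 3.86 ± 0.35, 3.36 ± 0.74 and 3.27 ± 0.28. Of 91 end genes 51 rose and 7 fell, and the median of 0.73 turns to -0.03 with MAD scaling.

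**Figure D4:**
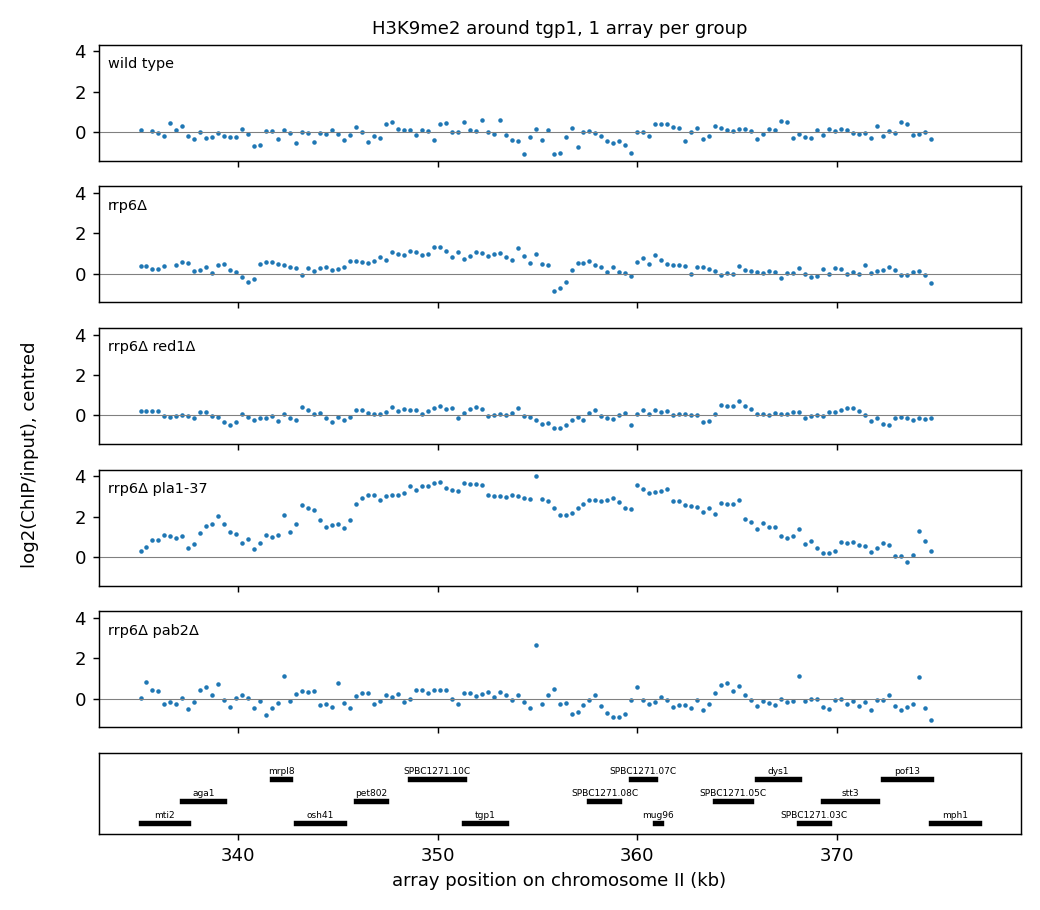
Centred log2 ChIP over input (y axis) along chromosome II around tgp1 (x axis, array positions in kb) for WT, rrp6∆, rrp6∆ red1∆, rrp6∆ pla1-37 and rrp6∆ pab2∆, with the genes drawn under the tracks. At tgp1 the level is 3.58 in rrp6∆ pla1-37 against 0.97 in rrp6∆ and 0.08 in WT.

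The largest falls were glm2 (-4.38 ± 0.18), mme1 (-4.23 ± 0.23), ste6 (-4.18 ± 0.41), rmr1 (-4.09 ± 0.40), mic26 (-3.24 ± 0.09), pre8 (-2.63 ± 1.02), pvg2 (-2.11 ± 0.21) and lcb4 (-2.05 ± 0.40). The lost domains around ste6 (III 1759800 to 1793400, -1.78), plb5 to SPCC1450.12 (III 1743300 to 1758000, -0.84), pvg2 with Tf2-6 (I 4011600 to 4030800, -1.23), myp2 (I 2547300 to 2561700, -1.47) and SPCC569.05C (III 2427000 to 2439300, -1.06) were the longest. All 9 Tf2 elements fell (median -2.13). Of the followed gains nab2 (-0.54), mug5 (-0.48) and avl9 (-0.27) did not pass the call, and cbm1 (2.39 ± 1.32) and cao1 (0.66) cannot be read because their input was nearly absent.

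In the mating list 4 genes fell, among them spk1 (-0.98 ± 0.26) and ste4 (-0.72 ± 0.51). In the recombination list rec6 (-0.73 ± 0.22) and spo4 (-0.59 ± 0.45) fell and isp3 rose (1.03 ± 0.32). No Mmi1 and Red1 target passed, with num1 at -0.78 ± 0.57. Of the mug genes 4 rose and 5 fell, as mug165 (1.20 ± 0.23) and mug133 (-0.82 ± 0.43). Other members that rose were ght3 (1.49 ± 0.54), the iron transporter gene str3 (0.76 ± 0.50), the permease genes put4 (0.67) and isp5 (0.66), gpd1 (0.77) and clr4, the H3K9 methyltransferase gene (0.59 ± 0.26), while pho84 (-0.64 ± 0.07), swi6 (-0.61 ± 0.33), ura4 (-1.05 ± 0.16) and lys1 (-0.61 ± 0.28) fell. Of the control lists 11 of 51 ribosomal protein genes (rpl3002 at 1.81, inside the red1 block, rps7 at 1.22, rpl14 at 1.19) and 2 of 15 housekeeping genes (eno101 at 1.17 ± 1.41, adh1 at 0.82 ± 0.72) rose. The pericentromeres lay lower, by a median of -1.62, and so did the mating-type contig, by -0.85, and both signs held under every scaling tried. With mode centring 247 genes were higher and 145 lower, and with loess 268 and 163. In the simulation 345 of 4179 unchanged genes (8.26%) passed, a number close to that of the calls. The simulated gene spread came from these same differences, so the closeness is partly built in. Beyond the largest differences and the long blocks, the calls cannot be told from spread. This array is on slide 3 and rrp6∆ on slide 1. A slide effect is argued against for the 2 long blocks, over which rrp6∆ pab2∆ on the same slide had medians of -0.20 (red1) and -0.04 (tgp1) against 2.73 and 2.77 in rrp6∆ pla1-37. For changes that both arrays of the slide share, genotype and slide cannot be told apart.

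The comparison of rrp6∆ pab2∆ with rrp6∆ asks which H3K9me2 depends on the nuclear poly(A)-binding protein. Here the rrp6∆ gains went back towards WT, and the chromosome ends lost H3K9me2 as well. Over the 114 gains the median was -0.96 (-1.06 to -0.82) from rrp6∆ and 0.05 (0.00 to 0.10) from WT (0.31 with series matrix values), with 83 genes lower and 0 higher. The ends lay lower than in rrp6∆ by a median of -0.84, and lower under every scaling tried, the largest differences being at SPAC750.06C (-3.88 ± 0.55), SPAC212.04C (-3.59 ± 0.25) and SPAC750.01 (-3.55 ± 0.42). Of 91 end genes 45 fell and 0 rose. On the same slide rrp6∆ pab2∆ lay below rrp6∆ pla1-37 over the gains by a median of -0.26 (-0.38 to -0.17).

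Of 4594 genes measured, 132 fell outside constitutive heterochromatin, and of 208 inside it 62 fell and 0 rose. The largest falls outside it were glm2 (-4.92 ± 0.28), ste6 (-4.68 ± 0.42), rmr1 (-4.61 ± 0.60), mme1 (-4.47 ± 0.36), mic26 (-3.86 ± 0.24), pre8 (-2.72 ± 1.16), lcb4 (-2.61 ± 0.75) and myp2 (-2.47 ± 0.54). In contrast to rrp6∆ ago1∆, avl9 fell too (-2.46). The longest lost domains lay around ste6 (III 1758600 to 1788900, -2.15), Tf2-3 with cao1 (I 2927700 to 2948700, -1.79), pvg2 (I 4011600 to 4031700, -1.04), myp2 (I 2547000 to 2562300, -2.25) and man1 to mug5 (I 5229300 to 5242200, -1.74). All 9 Tf2 elements fell (median -2.05). List members that fell were mek1 (-0.66), spk1 (-0.60), rec6 (-0.68), mde2 (-0.60), mug5 (-1.14 ± 1.01), mug100 (-0.76), mug184 (-0.71), tgp1 (-0.67), ght7 (-0.76), per1 (-0.83), rpl1001 (-0.89) and lys1 (-1.37). Of the 79 mug genes measured 3 fell and 2 rose.

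The 97 genes that rose formed no long domain, the longest measuring 3.3 kb (plb2, ght8, and new25 with pmp20). They were led by wwm2 (1.83 ± 0.87), the peroxiredoxin gene pmp20 (1.48 ± 0.44), ngl1 (1.25 ± 1.02), ypf1 (1.24 ± 1.56), knh4 (1.17 ± 0.64), sum2 (1.13 ± 1.39), zng1 (1.10 ± 0.72) and rsa1 (1.07 ± 0.69). After them came ptf2 (1.05), pre5 (1.02), the thiamine-repressed gene nmt1 (1.01) and erg10 (1.01). Among lists, gpd1 (0.88 ± 0.51), 7 of 51 ribosomal protein genes (rpl14 at 0.91) and 2 of 15 housekeeping genes (pyk1 at 0.85, eno101 at 0.65) rose, and no metal or RNAi gene passed. The pericentromeres lay lower by -0.93 and the mating-type contig by -0.44, signs that held under every scaling tried. The higher and lower counts were 155 and 112 with mode centring and 171 and 139 with loess, and the simulation gave 172 calls among 4186 unchanged genes (4.11%). For changes shared with rrp6∆ pla1-37, genotype and slide cannot be told apart here either. The array correlated by rank with its slide neighbour rrp6∆ pla1-37 at rho 0.598, with rrp6∆ at 0.314 and with ago1∆ in low glucose, on slide 5, at 0.610. Raw ChIP medians were low in rrp6∆ pab2∆ (2527.5), rrp6∆ pla1-37 (2282) and ago1∆ in low glucose (1235), against 14575.5 in rrp6∆. WT in low glucose, at 1439, correlated with rrp6∆ pab2∆ at 0.316. These correlations neither show nor exclude a slide effect or another technical cause. Some single probes, however, stood far above their neighbours in several arrays. At III 1781100 the levels were 2.79 in rrp6∆ pla1-37, 2.84 in rrp6∆ pab2∆ and 3.84 in ago1∆ in low glucose. At the next probe they were -0.476, -0.432 and -0.125. At II 354900 rrp6∆ pab2∆ and ago1∆ in low glucose read 2.65 and 1.65. Such peaks shared across genotypes and slides go with a technical cause at these probes. Whether they underlie rises such as those of ypf1 and sum2 was not tested. The histone-free mitochondrial probes differed from rrp6∆ by 0.96 in rrp6∆ pab2∆ and by 0.91 in rrp6∆ pla1-37 (-0.98 and -2.05 with loess).

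The comparison of WT in low glucose with WT asks how H3K9me2 responds to the growth condition. H3K9me2 rose at several meiotic genes, at genes of the rep1 block and over the chromosome ends. The ratio fell at other genes, among them hmt1 and ssa2. Such falls need not be a loss of the mark: the housekeeping list went from a median level of -0.09 in WT to -0.56, below the array's centre. The meiotic genes num1 (2.27 ± 0.45), mug9 (1.86 ± 0.13), ssm4 (1.02 ± 0.24) and rep1, a transcription factor gene of early meiosis (1.81 ± 0.64), rose. The chromosome ends stood at 3.07 against 1.18, a median difference of 1.60 that was above 0 under every scaling tried. The mitochondrial probes, which have no histones, also lay higher, by 1.43 (19 probes, -1.97 with loess), about as much as the ends. Medium (EMM against YEA), glucose (0.5%, with the other level not given), and slide all differ between the arrays.

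Of 3614 genes measured, 244 rose and 322 fell outside constitutive heterochromatin, and of 195 inside it 160 rose and 0 fell. Next to num1 stood but1 (2.24 ± 0.32) beside ssm4, SPCC70.08C beside mug9 (1.95 ± 0.22), alr2 (1.90 ± 0.55), exg3 (1.82 ± 0.68) and aly2 (1.64 ± 0.41) beside rep1, SPBC1711.15C (1.60 ± 0.10) and the recombination mediator gene sfr1 (1.52 ± 0.23). The malic enzyme gene mae2 (1.94 ± 0.80) and the malate permease gene mae1 (1.69 ± 1.68) also rose, but stand at -1.58 and -1.82 with MAD scaling and at -1.43 and -1.94 with loess. The longest gained domains were SPCC569.05C to SPCC569.01C (III 2427300 to 2454000, 26.7 kb, 1.49), his2 to rec15 and beyond (II 2161200 to 2181000, 1.15), abc3 with mug14 (II 114300 to 130200, 1.25), aly2 to mmp1 around rep1 (II 2972100 to 2981400, 1.73) and SPCC569.07 (III 2417400 to 2424000, 0.96).

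Of 12 Mmi1 and Red1 targets 4 rose and 0 fell (median 0.34). Further members that rose were the recombination genes rec6 (0.89 ± 0.25), rec11 (0.60 ± 0.54) and rec12 (0.59 ± 0.43), mug143 (1.18 ± 0.48), mug5 (1.10 ± 0.50), the hexose transporter genes ght7 (1.74 ± 0.21) and ght3 (0.75 ± 0.51), str3 (1.15 ± 0.47), the permease genes cat1 (1.20 ± 0.34) and per1 (1.01 ± 0.15), and the markers ura4 (1.39), his2 (1.27) and lys1 (0.71). Of these, rec6, ght7, ght3, str3, cat1, per1 and lys1 lie in constitutive heterochromatin, and without its members there the hexose list median was -0.20 with 0 genes called. Of the 58 mug genes measured 5 rose and 3 fell (median 0.01). Outside constitutive heterochromatin 2 permease genes rose and 1 fell, and the recombination list median was -0.06. All 9 Tf2 elements rose (median 0.88, Tf2-4 at 0.99 ± 0.22), but the Tf2 median is -0.07 with normexp background and -3.71 with loess. Of 86 end genes 77 rose and 0 fell, SPAC186.06 by 3.73 ± 0.04, SPAC186.07C by 3.60 ± 0.17 and SPAC186.08C by 3.32 ± 0.11. The pericentromeres lay higher by 1.11 and the mating-type contig by 1.34, but at -2.54 and -0.91 with MAD scaling and at -1.83 and -0.67 with loess.

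Genes that fell included hmt1, a vacuolar transporter gene (-1.88 ± 0.89), SPAC29A4.02C (-1.52 ± 0.21), ssa2, an Hsp70 gene (-1.51 ± 0.24), the sulfate permease gene sul1 (-1.50 ± 0.37), the fumarase gene fum1 (-1.46 ± 0.21), atd1, an aldehyde dehydrogenase gene (-1.44 ± 0.26), meu7 (-1.34 ± 0.05) and mbx2 (-1.33 ± 0.06). Of 13 housekeeping genes 5 fell and 0 rose (median -0.41), among them adh1 (-1.27 ± 0.62), tpi1 (-0.92 ± 0.55) and tdh1 (-0.92 ± 0.44), and ste7 fell in the mating list (-0.91 ± 0.41). Lost domains lay over pdp3 to gpd2 (I 4332300 to 4338900, -0.76), adh1 (III 1589100 to 1594800, -1.12), agp3 (III 2305500 to 2311200, -0.78), sul1 (II 1886100 to 1891800, -1.03) and igo1 (I 1235700 to 1241100, -0.75). No phosphate, stress or RNAi gene of the lists passed, and 2 of 22 ribosomal protein genes rose, both in constitutive heterochromatin (rps402 at 0.90), and 1 fell.

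The median of all genes outside constitutive heterochromatin was -0.09, and it moved to 0.03 with mode centring and -0.24 without centring. The higher and lower counts were 357 and 185 with mode centring, 140 and 583 without centring and 67 and 41 with MAD scaling. The simulation without change gave 542 calls among 3219 genes (16.8%), close to the number observed. Since it took its gene spread from the observed differences, this closeness is partly built in.

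**Figure D5:**
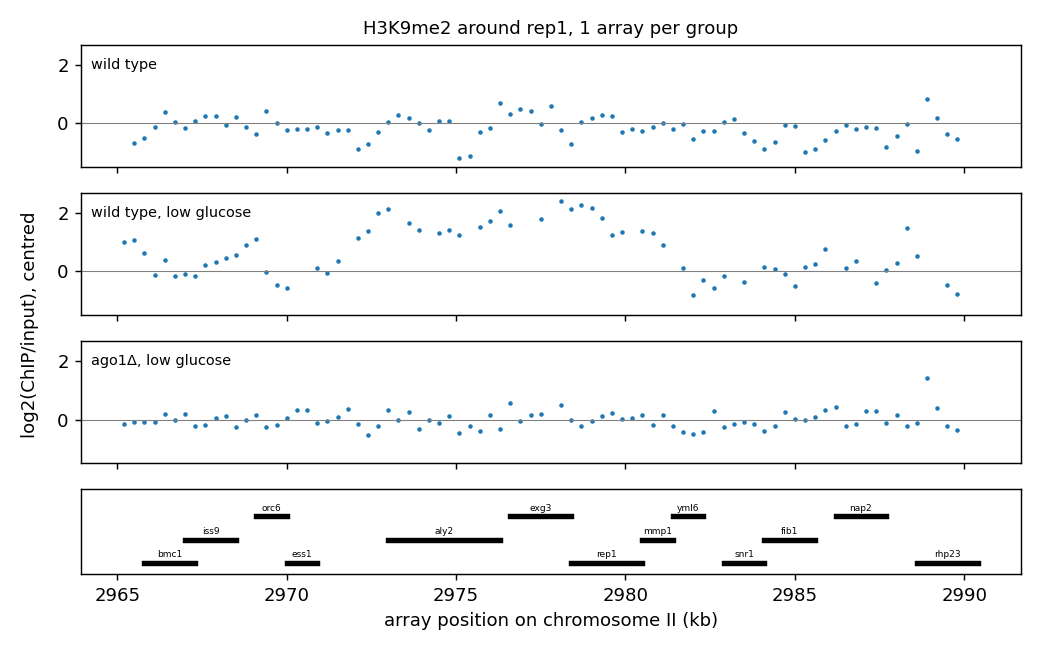
Centred log2 ChIP over input (y axis) along chromosome II around rep1 (x axis, array positions in kb) for WT, WT in low glucose and ago1∆ in low glucose, with the genes drawn under the tracks. At rep1 the level is 1.98 in WT in low glucose, 0.05 in WT and 0.01 in ago1∆ in low glucose.

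The comparison of ago1∆ with WT, both in low glucose, asks whether the low glucose pattern depends on Argonaute. The meiotic genes that carried H3K9me2 in low glucose fell without ago1, as did the rep1 block and the Tf2 elements. Of 12 Mmi1 and Red1 targets 7 fell and 0 rose (median -0.72), a median below all 10000 matched random lists. The fall was 2.62 ± 0.27 at mei4 (from 4.40 to 1.87), 2.46 ± 0.43 at mug9, 2.25 ± 0.33 at ssm4 and 2.06 ± 0.45 at num1, and rep1 fell by 1.92 ± 0.57. Over the genes gained in low glucose, the median was -0.58 (-0.66 to -0.52, 242 genes) from WT in low glucose and 0.18 (0.12 to 0.22) from WT, with 116 genes lower and 3 higher. In simulated arrays without any change, genes selected as gains in the same way had medians of -0.64 (central 95% of simulations -0.68 to -0.61) and 0.12, and 59.8% of them were lower. These simulations have the observed spread, so the medians cannot tell an effect of ago1 from selection. A deviation of the WT low glucose array alone would also return genes to the WT level, as at rep1 (0.05 in WT and 0.01 in ago1∆ in low glucose). At mei4 and ssm4 the levels without ago1 (1.87 and 1.89) lay below those of the WT array as well (3.88 and 3.32), but not below those of the WT column of the series matrix (1.58 and 0.88).

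The largest fall of all was at ura4 (-6.40 ± 0.53). With the meiotic genes fell but1 (-2.48 ± 0.45) and SPCC70.08C (-1.71 ± 0.51), and in the lists per1 (-3.11 ± 0.87), lys1 (-2.08 ± 0.41), rec11 (-1.10 ± 0.87), rec12 (-0.65 ± 0.29), mde2 (-0.74 ± 0.21) and mug100 (-0.96 ± 0.42). Of the 58 mug genes measured 5 fell and 6 rose. All 9 Tf2 elements fell (median -1.08, Tf2-4 at -1.31 ± 0.33). Lost domains lay over ubr11 to bud6, which holds sgo2 (I 3709200 to 3718800, -0.97), aly2 to mmp1 around rep1 (II 2972100 to 2981400, -1.65), pta1 (I 3847800 to 3855300, -0.77), rec11 (III 1218600 to 1225800, -0.97) and lig4 (III 596700 to 602700, -0.90). At the pericentromeres the median difference was -0.54, against -3.58 in the rrp6∆ background (the difference between the backgrounds was not tested), and 2.81 with MAD scaling. The mitochondrial probes differed by -1.01 (19 probes).

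Of 3618 genes measured, 357 rose and 181 fell outside constitutive heterochromatin, and of 196 inside it 24 rose and 72 fell. The genes that rose were led by lsd90 (2.25 ± 0.69), meu7 (1.64 ± 0.21), SPCC757.02C (1.53 ± 0.70), vip1 (1.51 ± 0.22), atd1 (1.48 ± 0.15), tim21 (1.46 ± 0.56), ggt2 (1.44 ± 0.58), SPAC29A4.02C (1.37 ± 0.10), lys9 (1.37 ± 0.10), the UDP-glucose epimerase gene uge1 (1.35 ± 0.24), sgt1 (1.33 ± 0.54) and ede1 (1.32 ± 0.59). Of these, meu7, atd1 and SPAC29A4.02C were among the largest falls of WT in low glucose. At the ends the galactose genes gal1 (3.44 ± 0.42) and gal7 (3.12 ± 0.14) and tgd1 (2.94 ± 0.24) rose, with 17 higher and 5 lower of 87 end genes. Gained domains lay over SPCP20C8.01C with SPCP20C8.02C (III 16800 to 33000, 1.10), SPCC569.03 to SPCC569.01C (III 2430600 to 2440500, 0.99), cts1 (I 1207200 to 1216200, 0.75), spk1 with pac2 (I 3000300 to 3007800, 0.70) and pfk1 (II 2296200 to 2303700, 0.93).

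In the lists pho1 (1.91 ± 0.29) and pho84 (1.29 ± 0.23), both of the 2 phosphate genes measured and both at the chromosome end, rose. So did ctt1 (0.80), fbp1 (0.65), clr4 (0.62), ste7 (0.65), sxa1 (0.60), the ammonium transporter gene amt2 (0.62 ± 0.84), arg3 (1.06), 4 of 22 ribosomal protein genes and 5 of 13 housekeeping genes (tdh1 at 1.12, eno101 at 1.11, adh1 at 1.08). The rise of the housekeeping list went from a median level of -0.56 in WT to -0.05 in ago1∆, near the array's centre. No hexose or metal transport gene passed. With MAD scaling 118 genes were higher and 36 lower. In the simulation 487 of 3222 unchanged genes (15.1%) passed, close to the number observed, which its gene spread partly builds in. Each low glucose array is alone on its slide, so that genotype and slide cannot be told apart.

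The gains of rrp6∆ and of low glucose shared 26 genes of 92 and 244 called among the 3415 genes measured in both. Independent lists of these sizes would share 6.57, and lists of the same sizes from simulated unchanged arrays compared with the same WT array shared 17.0 on average (central 95% of simulations 10 to 24.0). The 26 were the 9 Tf2 elements with smn1, mug143, obr1, iec1, vps28, mug5, sls1, SPBC359.01, alr2, aat1, SPBC1683.02, brx1, SPCP20C8.02C, ggc1, ero12, glm2 and SPCC569.01C. With the WT column of the series matrix in place of the WT array for low glucose, 16 genes of 92 and 265 were shared, where independent lists would share 7.14. The shared count was 5 with loess, 10 with MAD scaling, 15 without non-unique probes, 97 with series matrix values and 2 with a 2-fold threshold. The 9 Tf2 elements among the 26 are repeats, left out with the non-unique probes, while the expected counts take every gene as separate. The 26 therefore cannot be read as lying above the simulated range. In low glucose these elements had a median of -3.71 with loess. The lower genes shared 2 (pre6 and mug33, against 1.13 for independent lists and 3.37 in the simulation). The covariance of the differences across genes was 0.0269 against 0.0202 in unchanged simulated arrays, and 0.00387 with separate WT values, while the correlation was 0.178 against 0.257 in the simulation, and 0.0239 with separate WT values. Part of the sharing may come from the common WT array.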

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

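Of the tests weighed here, those of copy number at ste6 against rrp6∆, probe noise and repeated probes were planned before their results were seen, and the others were chosen after.

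The ste6 block kept its H3K9me2 in rrp6∆ red1∆ while most other gains of rrp6∆ fell. Retained red1 is argued against by the input at red1 (-8.82), and a copy number change against rrp6∆ by the input over ste6, glm2, mme1 and rmr1 (-0.068, SD 0.39, 33 probes). In both arrays this input lay below WT (-1.27 in rrp6∆ and -1.35 in rrp6∆ red1∆), for reasons left open. The opposite movement is not particular to ste6: at mei4 in rrp6∆ against WT the ChIP channel changed by -2.33 and the input by 1.12. At ura4 in low glucose against WT, however, both rose (2.18 and 0.94). A copy number change shared by both arrays would lower the ChIP channel too, but that channel lay 3.30 above WT in rrp6∆ red1∆ (interval 2.95 to 3.74). Mixing with rrp6∆ chromatin would keep other gains alike, but their median share kept was 18.6% (interval 11.9 to 31.3, 100 genes) against 104% over the 4 core genes, and a larger scale of the array would raise the pericentromeres, which lay at -0.30. A step at ste6 that needs Ago1, Pla1 and Pab2 but not Red1 may explain the pattern, as an untested hypothesis from 1 array per strain, confounded with slide, that ChIP at ste6 in replicate cultures of the double mutants could test.

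In WT in low glucose 322 genes fell against WT, a count that was 185 with mode centring and 41 with MAD scaling. Intensity-dependent dye bias is argued against as the whole cause, since with loess these genes had a median of -0.63 (interval -0.65 to -0.61). Outlier probes had been left out of the calls, so their own values did not make them. With those probes kept the median was -0.68 (-0.71 to -0.64), but it still includes the probes used for the call. It therefore cannot show whether what marked the outliers also affected the other probes. Only 180 of the 322 were still called with outlier probes kept, and 194 with loess. Noise selected by the call would vanish on other probes, but genes called lower on odd probes had a median of -0.47 on even probes (interval -0.62 to -0.42, 92 genes). In ago1∆ in low glucose the same genes lay at -0.045 from WT (SD 0.20, interval -0.07 to -0.02, 322 genes). A deviation of this 1 array would give that, and also the return of the gained genes to 0.18 from WT. The 54 gains of at least 2-fold shared with the main call did not return fully. They lay at 0.44 from WT (interval 0.21 to 0.67), with 23 genes higher and 3 lower. Both low glucose arrays were compared with the same WT array. Dependence on ago1 stays open, untested and confounded with slide.

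The pericentromeres lost more H3K9me2 without ago1 in the rrp6∆ background than in low glucose. Retained ago1 in the low glucose strain is argued against by its input (-9.81), a failed ChIP in rrp6∆ ago1∆ by the mating-type contig and the ends, the lower of which lay at 0.77, and saturation by 0% saturated spots among 360 probes. Whether repeated probes that read other copies hide a loss cannot be decided: probes without repeat suffixes lay at -1.40 in low glucose (interval -2.33 to -0.73, 74 probes, SD 1.93) and at -3.03 in the rrp6∆ background (77 probes, SD 1.31). The MAD-scaled value in low glucose was 2.81. Medium, genotype and slide differ between these pairs, and a biological difference between them remains open and untested.

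Other results drew attention because the effect had opposite directions in different groups, and these differences between groups were not tested. Over the SPCP20C8.02C domain, the effects of removing ago1 and red1 from rrp6∆ lay 1.82 apart. The effect of ago1 in rrp6∆ minus its effect in low glucose was 1.03 at the mating-type contig, 1.78 at the pNSU clones and 1.28 at the mitochondrial genome. With MAD scaling the effects at the contig and the clones changed direction in both groups.

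A signal in values outside the comparisons also drew attention. In the WT column of the series matrix, which is not the WT scanner file, the median level of mei4, ssm4, mcp7, SPAC8C9.04 and mug9 was 0.88, with mei4 at 1.58 against 3.88 in the scanner file.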

How the results depend on the processing

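Each of 31 main results and 187 values of named genes was recomputed under the alternatives that apply to it (19 settings, 3467 values). Keeping the outlier probes, moving the registration and leaving out genes with lost input were chosen after seeing the data. Of the main results 397 values stayed within the limits set for calling them unchanged and 79 moved. Of the gene values 2710 stayed, 267 moved and 14 reversed. MAD scaling moved 94 gene values, normexp 70, loess 37 and the series matrix 20. Except where a reason is given, the cause was not tested. No paired analysis was possible because each group has 1 array. Raw ChIP medians ran from 1235 to 15372.5, and 1 to 16 probes per array were not well above background in the ChIP channel.

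With normexp background, lower genes in rrp6∆ against WT numbered 34 and higher genes in rrp6∆ ago1∆ 172. The higher and lower counts were 194 and 197 in rrp6∆ red1∆, 396 and 330 in rrp6∆ pla1-37 and 273 and 234 in rrp6∆ pab2∆. The median of rrp6∆ pab2∆ minus WT over the rrp6∆ gains was 0.12, and that of ago1∆ minus WT in low glucose over the low glucose gains -0.48. In rrp6∆ pla1-37, cbm1 reversed to -2.57 and cao1 to -3.36, where the input was nearly absent.

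With mode centring, 155 genes were higher in rrp6∆ pab2∆, 185 genes and 64 domains were lower in low glucose, and the median of rrp6∆ ago1∆ minus WT was 0.085. Without centring, 140 genes were higher and 583 lower in low glucose, with 310 domains lower.

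With MAD scaling, 17 domains were lower in rrp6∆, 51 genes higher in rrp6∆ ago1∆ and 46 higher in rrp6∆ red1∆. In low glucose 67 genes were higher and 41 lower, with 73 domains higher and 32 lower. In ago1∆ in low glucose 118 genes were higher and 36 lower, and the median over the low glucose gains was -0.32. The overlap of gains was 10 genes. In low glucose mae2 reversed to -1.58 and mae1 to -1.82, in rrp6∆ red1∆ rmr1 reversed to 0.57, and in rrp6∆ pla1-37 cao1 reversed to -0.28.

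With loess, WT had 71 domains, 171 genes were higher in rrp6∆ pab2∆ and 161 in low glucose, the overlap was 5 genes, and the median of rrp6∆ ago1∆ minus WT was 0.080. In low glucose mae2 reversed to -1.43 and mae1 to -1.94, and in rrp6∆ red1∆ mme1 to -0.035 and ste6 to -0.0064.

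With the series matrix, 205 genes were higher and 28 lower in rrp6∆, with 126 domains higher, 212 genes were lower in rrp6∆ ago1∆, and the overlap was 97 genes. In rrp6∆ ura4 reversed to 0.96 and pre6 to 0.29. The median over the rrp6∆ gains was 0.084 for rrp6∆ ago1∆ minus WT. It was -0.42 and 0.42 for rrp6∆ red1∆ minus rrp6∆ and minus WT, and -0.50 and 0.31 for rrp6∆ pab2∆. The matrix holds another WT column than the scanner file.

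With a 2-fold threshold, which is stricter for each gene but also shrinks constitutive heterochromatin, WT had 62 domains. The higher and lower gene counts were 58 and 6 in rrp6∆ (35 and 9 domains), 11 and 53 in rrp6∆ ago1∆, 0 and 34 in rrp6∆ red1∆, 46 and 37 in rrp6∆ pla1-37 and 12 and 52 in rrp6∆ pab2∆. They were 70 and 38 in low glucose (99 and 7 domains) and 61 and 50 in ago1∆ in low glucose, and the overlap was 2 genes. Genes that the main call had left out entered: 54 of the 70 higher in low glucose were shared with it, 9 of 11 higher and 48 of 53 lower in rrp6∆ ago1∆, and 59 of 61 higher and 41 of 50 lower in ago1∆ in low glucose, while the other gene lists were shared in full. The medians over the gains were -1.37 for rrp6∆ ago1∆ minus rrp6∆ (0.093 minus WT), -1.06 for rrp6∆ red1∆, -1.14 for rrp6∆ pla1-37, -1.57 for rrp6∆ pab2∆ and -0.52 for ago1∆ in low glucose (0.65 minus WT). Over the 54 shared genes the last were -0.68 and 0.44.

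With 2 probes per gene and 3 per domain, which is looser by construction, 120 domains were higher and 67 lower in rrp6∆, 22 genes higher in rrp6∆ red1∆ and 518 domains higher and 392 lower in low glucose. Without non-unique probes, 16 domains were lower in rrp6∆ and the overlap was 15 genes, since repeats such as Tf2 are left out. With flanks, pre6 in rrp6∆ reversed to 0.10 and the median over the low glucose gains was -0.50. On even probes of genes selected on odd probes that median was -0.48. With outlier probes kept, 325 domains were lower in low glucose. With the registration moved by 150 bp, cao1 in rrp6∆ pla1-37 reversed to -0.13. The runs without dim probes, with a running mean and without genes with lost input moved no main result beyond the limits.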

Other observations

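The test of the hypothesis given last was chosen after its result was seen. Genes at the edge of pericentromere I, in a WT domain of 55.2 kb (I 3723900 to 3779100) that overlaps it, carried H3K9me2 that was lower without ago1 in both backgrounds. The amino acid permease gene per1 stood at 3.18 in WT and 3.42 in rrp6∆ but at 0.17 in rrp6∆ ago1∆, and at 4.25 in WT in low glucose but at 0.95 in ago1∆ in low glucose. The lysine gene lys1 stood at 1.60 in WT, 2.46 in rrp6∆ and -0.07 in rrp6∆ ago1∆, and at 2.33 and 0.33 in low glucose without and with ago1∆. At pla1, whose product is altered in rrp6∆ pla1-37, the difference from rrp6∆ in that array was -0.11, and no comparison called the gene.

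The pNSU clones, which hold subtelomeric sequence, had median levels of 4.37 in WT, 3.70 in rrp6∆, 4.81 in rrp6∆ ago1∆, 4.39 in rrp6∆ red1∆, 2.67 in rrp6∆ pla1-37, 3.24 in rrp6∆ pab2∆, 6.93 in WT in low glucose and 6.01 in ago1∆ in low glucose. Probes of the mitochondrial genome, which has no histones, lay at -1.75 in WT and between -1.75 and -0.20 in the 7 other arrays. Over the 114 genes gained in rrp6∆ the ChIP channel changed by a median of 0.90 and the input by -0.16, and over the low glucose gains these changes were 0.81 and 0.091.

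The marker ura4 stood at 6.27 in WT, 5.24 in rrp6∆, 0.23 in rrp6∆ ago1∆, 7.50 in WT in low glucose and 1.21 in ago1∆ in low glucose. Heterochromatin spread over its native locus is argued against, since probes within 5 kb had a median of -0.19 in WT (SD 0.71, 30 probes). A candidate explanation is a copy of ura4 placed as a reporter inside heterochromatin, as is common in laboratory strains. The labels name no such reporter, and the arrays cannot locate one.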
